A study of Mus musculus with 9 samples.

How the data were processed

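The 9 libraries, 5 of wild type and 4 of SMN delta 7 (SMA) mice, were made from total RNA of hindlimb skeletal muscle. Per the labels' protocols, 200 ng of RNA with an integrity number above 7 entered a stranded mRNA preparation, which selects polyadenylated RNA and keeps the strand, and the libraries were sequenced as paired reads of 75 bases on a HiSeq instrument. Per the submitters' processing notes, HTSeq 0.9.1 and DESeq2 1.16.1 were used with the genome build mm10, with no role stated for either tool. The aligner, the annotation and the strand setting of the counting are not given in the sources used here.

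The deposited count table holds whole-number counts per gene and library, not normalized, for 32594 genes, of which 9145 had no count in any library. The authors' second deposited table holds a signal per gene and library, which is each count divided by 1 size factor per library. Dividing the counts by these values gave factors from 0.734 to 1.23, equal to median-of-ratios size factors computed from the counts. No library column was left unused. Replicates were compared for duplicates by a chi-square test of their counts, and no pair within a group agreed within sampling noise, with chi-square values per degree of freedom from 12 to 87.5.

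Groups and replicate numbers were taken from the labels. The comparison of SMA with wild type, its test, the gene lists and most alternatives were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with group as its 1 term was fitted to all 9 libraries, with Benjamini-Hochberg adjustment over 15873 genes and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the quasi-likelihood F statistic. CPM values are counts-per-million of the scaled library size, and log2 CPM used a prior count of 2. Library measures and myosin shares were compared by two-sided exact permutation tests over the 126 divisions of the 9 libraries. Those tests were adjusted over 7 library measures and over 6 myosin genes. Myosin shares and shares of abundant and haemoglobin genes need no scaling. Numbers of detected genes grow with depth, so they were also counted after random thinning of every library to 24917665 counts.

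In all, 39 gene lists were fixed, covering the SMN complex, ribonucleoprotein assembly, denervation, the neuromuscular junction, atrophy, p53, fibre types, development, myogenic regulators, metabolism, the clock, glucocorticoids, the cell cycle, matrix, stress, interferon, growth factors, sterols, 14 cell types and 2 quality sets. Of 733 listed members, 707 matched by symbol, 6 by an older name and 20 did not match. The list of mitochondrially encoded genes had no matching entry, so 38 lists were tested. Each was tested by camera of limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and by the rotation test fry. Some lists share members, such as Chrna1 in both the denervation and the neuromuscular junction list, so their results are not separate. The denervation list shares Cdkn1a with the p53 list, Mt2 with the glucocorticoid list, and Fbxo32 and Trim63 with the atrophy list. Klf15 and Cebpd are in the atrophy and glucocorticoid lists, Eda2r in the atrophy and p53 lists, and Sesn1 and Ddit4 in the p53 and glucocorticoid lists. Chrng, Ncam1 and Peg3 are in the denervation and developmental lists, and Per1 in the clock and glucocorticoid lists. The matrix list shares Col1a1 and Col3a1 with the fibroblast list, and Fmod, Thbs4 and Col11a1 with the tendon list. By fry, whose p asks whether genes of a list move one way on balance without comparing them with other genes, 26 lists passed at an unadjusted 0.05, and 36 by its mixed version, which asks for change in either direction.

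A rule fixed before the data were examined selected 79 genes. It took a set of disease and muscle genes whatever their values, the 6 largest rises and 6 largest falls among genes that passed, had a mean of at least 5 CPM in a group and did not overlap between groups, and, whether or not they passed, the 2 members of each biology list and the 1 member of each cell type or quality list with the lowest adjusted p. Others were chosen after their values were seen, among them Chrnd, Musk, Dach2, Actn3, Casq1, Myh1, Mki67, Col1a1, Mbp, Bglap, Lep, Igf2, Prodh, Per1, Ccng1, Tnnc2 and Col3a1. Some genes selected in these ways are not reported here. Gene positions are those of GENCODE M21 on the same build.

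Depth ranged from 24917665 to 35087722 counts per library. The procedure was tested on simulated counts drawn from the means and library sizes of these libraries, with 200 of 15873 genes changed. edgeR recovered 56.7% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 98.5% of those changed 4-fold, with 5 unchanged genes called. A simulated list of 20 genes shifted 1.5-fold had a camera p of 4.98e-28, and 2 of 100 unshifted lists fell under 0.05. Simulated genes were drawn independently of each other, and few were changed. In the measured data the estimated correlation was 0.33 for the cell cycle list and 0.72 for nuclear genes of oxidative phosphorylation. The simulation therefore cannot show how camera with the preset correlation behaves on the measured lists. Its recovery rates also need not hold for the measured data, where 54.9% of genes passed.

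Alternatives were other scalings (median-of-ratios size factors, upper quartile and total counts alone), no low-count filter or a stricter one of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, limma-trend on the log2 of the authors' normalized values plus 1, a replicate block, leaving out haemoglobin genes, sex as a covariate and leaving out each library in turn. Leaving out wild type 5 and SMA 3 together, and the comparison of myosin shares, with Myh2 and Myh7 and with libraries left out, were added after seeing the data, as were the count of detected genes after thinning and the level of Xist. Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9 was used for the region test and the plots.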

Results

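RNA was measured in 9 libraries of hindlimb skeletal muscle, 5 from wild type and 4 from SMN delta 7 mice, all on the FVB/N background. The SMN delta 7 mouse, called SMA here, is a model of spinal muscular atrophy, a disease in which too little survival motor neuron (SMN) protein leads to loss of spinal motor neurons and wasting of muscle. The comparison asked how the muscle transcriptome of SMA mice differed from that of wild type mice. Gene counts summed to 24917665, 30065776, 28581586, 29535292 and 34094645 in wild type libraries 1 to 5 and to 33035889, 35087722, 30746646 and 32671247 in SMA libraries 1 to 4. Mean totals were 29438993 ± 3288418 (SD, n = 5) and 32885376 ± 1778857 (SD, n = 4), a difference that did not pass (two-sided exact permutation test, p = 0.103, adjusted p = 0.103 over 7 library measures). Age and litter were not stated in the labels. Nothing in the labels says that each replicate came from its own animal, so every p-value measures the spread between these samples, which may be technical in part. Libraries with and without Y-linked expression occurred in each group, so neither group came from a single animal.

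Smn1, the mouse gene for SMN (chromosome 13, 100124852 to 100137690, plus strand, mm10), was measured first in every library. Its level was 13.1, 13.5, 13.8, 11.1 and 13.3 CPM (counts-per-million of the scaled library total) in the wild type libraries and 1.80, 2.24, 1.40 and 2.72 CPM in the SMA libraries. Smn1 fell by 2.66 ± 0.17 on the log2 scale (SE), with an adjusted p of 2.9e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The low level matched the labels in all 9 libraries. The allele structure is not in the labels, and reads of human SMN transgenes were not analysed here, so the Smn1 values of the SMA libraries may include such reads where they aligned to Smn1.

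Messenger RNA of the SMA muscle was spread over more genes. Libraries held 19832 ± 311 genes with at least 1 read in wild type (SD, n = 5) and 20587 ± 222 in SMA (SD, n = 4; exact permutation test, p = 0.00794, adjusted p = 0.0139). After every library was thinned to 24917665 counts, a comparison chosen after seeing the data, 19602 ± 274 and 20226 ± 284 genes had at least 1 read (exact permutation test, p = 0.0159). The 10 most abundant genes took 24.2% ± 1.69 of the counts in wild type and 18.6% ± 0.963 in SMA, with the same exact p of 0.00794, the smallest that 126 permutations can give. Haemoglobin genes took 0.174% ± 0.0429 of the counts in wild type and 0.0908% ± 0.0215 in SMA (exact permutation test, p = 0.0238, adjusted p = 0.0278). Y-linked genes were expressed in 4 of the 5 wild type libraries and in 1 of the 4 SMA libraries, and the X-inactivation transcript Xist was high in the remaining ones. Within each sex 1 group held a single library, so no comparison within a sex was made, and a fit with sex as a covariate was used in its place. On principal components of the tested genes the first component, with 63.8% of the variance, separated the groups, and SMA 3 lay apart from the other SMA libraries on the second, at -43.4 against 14.6 to 15.4.

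Much of the transcriptome differed, with lists of denervated muscle, proteolysis and p53 targets higher in SMA and lists of fast contraction, cell division and matrix lower by camera with a preset correlation, while 0 lists passed with an estimated correlation. The cell cycle inhibitor Cdkn1a rose 17.4-fold, from 38.7 ± 1.93 to 672 ± 165 CPM (SD, n = 5 and 4). The fast-fibre calcium buffer parvalbumin, encoded by Pvalb, fell 21.7-fold, from 19438 ± 4350 to 898 ± 204 CPM. Among 15873 genes tested, 4393 rose and 4319 fell in SMA (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), together 54.9% of those tested. At least a 2-fold change was found for 2309 genes, of which 1312 rose and 997 fell, and 274 rose and 194 fell at least 4-fold. The SMA and wild type libraries did not overlap for 7021 genes, or 44.2%, where chance gives 1.59%. Scaling to total counts alone, which shifted the median log2 fold change of all genes by 0.23, gave 6385 genes that rose and 2164 that fell, so that 74.7% of the calls rose against 50.4%, and changes are given relative to the scaling used throughout. With sex as a covariate 6883 genes passed, and without wild type 5 and SMA 3, the libraries farthest from their groups on the principal components, 9422 passed.

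The largest rises included ion channel, metal-binding and membrane genes. Chrna2, a subunit of neuronal acetylcholine receptors (chromosome 14, 66135039 to 66152948), rose by 5.90 ± 0.38 on the log2 scale (SE), from 0.105 to 6.73 CPM. Mt2, a metallothionein that binds zinc and copper, rose by 4.81 ± 0.24, and Sln, whose product sarcolipin inhibits the calcium pump of the sarcoplasmic reticulum, rose by 4.55 ± 0.39. The potassium channel gene Kcnt1 rose by 4.46 ± 0.46, and by 3.87 without SMA 3. Tmem82 (chromosome 4, 141613376 to 141618633, minus strand) rose by 4.46 ± 0.16 and AI507597, annotated as antisense within it (141614026 to 141615604, plus strand), by 4.80 ± 0.20, and how the counting treated strand is not stated, so their reads may be shared. The adjusted p-values of these 6 genes lay between 7.65e-09 for Tmem82 and 9.78e-06 for Kcnt1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

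Among the largest falls were a thermogenic gene and a glycogen synthase. Ucp1, the uncoupling protein of brown fat (chromosome 8, 83290352 to 83298452), changed by -5.59 ± 0.81 (SE), with 43.3 ± 43.9 CPM in wild type, where library 5 held 119 CPM. Without wild type 5 its change was -4.76, and without SMA 3 it was -6.28. Neu2, a cytosolic sialidase, fell by 5.43 ± 0.29, and Gys2, the liver form of glycogen synthase, fell by 4.73 ± 0.22. The neighbouring genes Gm4841 and F830016B08Rik on chromosome 18 changed by -5.49 ± 0.69 and -5.02 ± 0.97, and by -4.83 and -3.60 without wild type 5, and F830016B08Rik by -4.23 with limma-voom and -4.14 with limma-trend. C130080G10Rik, annotated as antisense (chromosome 2, 114054335 to 114064868, plus strand) beside the sarcomeric actin gene Actc1 (114047282 to 114053548, minus strand), fell by 5.22 ± 0.31. Their spans do not overlap in GENCODE M21. The annotation used in the counting is not stated, and whether reads were shared was not tested. Actc1 itself fell by 3.98 ± 0.20, from 5319 ± 1081 to 336 ± 63.2 CPM (SD, n = 5 and 4). The adjusted p-values of Neu2 (1.1e-07), Gys2 (5.2e-08) and F830016B08Rik (9.4e-04) came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

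**Figure D1:**
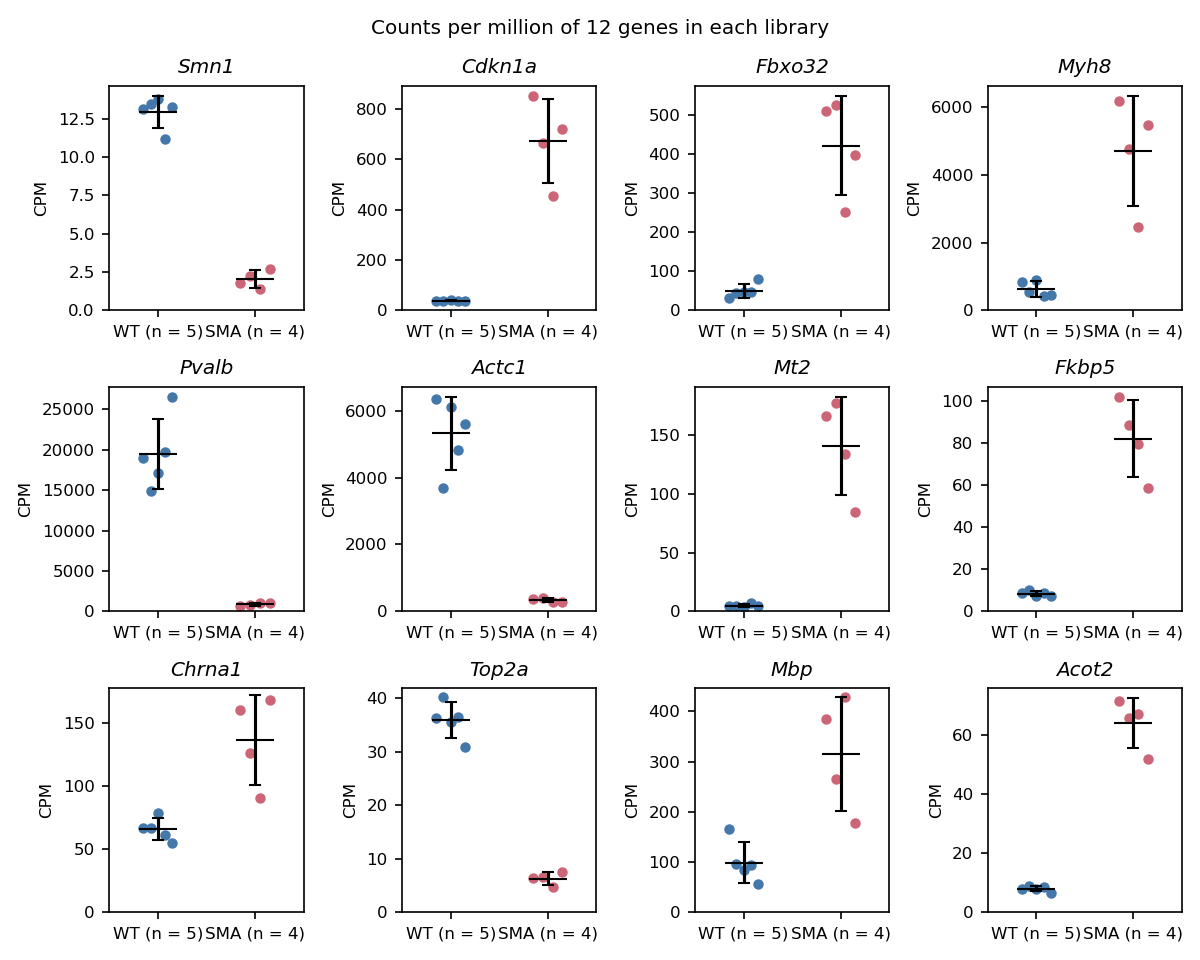
CPM, on the vertical axes, of 12 genes in each library, with points for libraries, horizontal bars for group means and error bars for SD (wild type n = 5, SMA n = 4). Smn1 lay between 11.1 and 13.8 CPM in the wild type libraries and between 1.40 and 2.72 CPM in the SMA libraries, and Cdkn1a lay between 36.4 and 41.7 CPM in wild type and between 454 and 849 CPM in SMA.

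Most measured members of the denervation list rose in SMA. Of 22 measured members of the denervation list, 14 rose, 3 fell and 5 did not pass (14 and 3 adjusted over the list alone). Chrna1, the alpha subunit of the muscle acetylcholine receptor, rose by 1.05 ± 0.16 on the log2 scale (SE), from 65.7 ± 8.84 to 136 ± 35.5 CPM (SD, n = 5 and 4). Dach2, a transcription cofactor gene, rose by 3.48 ± 0.40. Members of the list were fixed without a direction, so the rise of Dach2 by itself is not read as loss of nerve. Those that did not pass included Gadd45a at 0.13 ± 0.087, Runx1 at -0.0046 ± 0.15, Ankrd1 at 0.23 ± 0.14 and Rrad at -0.11 ± 0.20. Chrng, the fetal gamma subunit, had a log2 fold change of 0.49 ± 0.22 with an adjusted p of 0.0753 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It passed under scaling to total counts, with a log2 fold change of 0.70 at 0.0225, without SMA 2, at 0.0497, and without SMA 3, at 0.0381. Myog, a myogenic regulator that also rises after nerve injury in textbook accounts, fell by 0.41 ± 0.087, and lost its call under scaling to total counts, with an adjusted p of 0.084 by edgeR. By camera with a preset correlation of 0.01 the list was higher, with an adjusted p of 0.00143, and adjusted p = 0.467 with an estimated correlation.

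Neuromuscular junction genes were also higher on balance. Of 20 measured members, 11 rose, 1 fell and 8 did not pass (12 and 1 adjusted over the list alone). Colq, which anchors acetylcholinesterase at the synapse, rose by 1.36 ± 0.083 on the log2 scale, Chrnd by 1.20 ± 0.14 and the synaptic receptor kinase gene Musk by 0.87 ± 0.14. Chrnb1, the beta subunit of the acetylcholine receptor, was the 1 member that fell, with -0.79 ± 0.075. The list was higher by camera with an adjusted p of 0.00324, and adjusted p = 0.612 with an estimated correlation.

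Most measured members of the muscle wasting and p53 lists rose. In the atrophy and proteolysis list 20 of 26 measured members rose, 1 fell and 5 did not pass (20 and 1 adjusted over the list alone). The muscle ubiquitin ligase genes Fbxo32 and Trim63 rose by 3.05 ± 0.26 and 1.23 ± 0.20, the lysosomal protease gene Ctsl by 1.72 ± 0.082 and the ubiquitin ligase gene Cblb by 1.69 ± 0.094. Mstn, the growth inhibitor myostatin, was the member that fell, with -1.70 ± 0.20. Camera gave an adjusted p of 5.7e-06 for this list, and adjusted p = 0.467 with an estimated correlation. Of 24 measured p53 targets, 18 rose, 4 fell and 2 did not pass (18 and 4 adjusted over the list alone), with Cdkn1a at 4.12 ± 0.16 and Phlda3, an inhibitor of Akt signalling, at 2.49 ± 0.13 among those that rose and Ccng1 at -1.16 ± 0.17 among those that fell. The p53 list had a camera adjusted p of 3.63e-04, and adjusted p = 0.467 with an estimated correlation.

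Fast-fibre genes were lower in SMA, while slow-fibre genes were divided between members that rose and members that did not pass. Of 15 measured fast contractile genes, 12 fell, 1 rose and 2 did not pass (13 and 1 adjusted over the list alone). The log2 fold change was -4.44 ± 0.23 for Pvalb, -2.77 ± 0.18 for the myosin-binding protein gene Mybpc2, -2.24 ± 0.15 for the calcium store gene Casq1 and -2.19 ± 0.15 for the fast Z-disc gene Actn3. The troponin gene Tnnc2 fell by 0.92 ± 0.12. The fast list was lower by camera with an adjusted p of 3.67e-05, and adjusted p = 0.467 with an estimated correlation. Of 14 measured slow contractile genes, 8 rose, 0 fell and 6 did not pass (8 and 0 adjusted over the list alone), including Csrp3, a Z-disc protein gene, at 1.65 ± 0.20 and the myosin gene Myh7b at 1.71 ± 0.26. Main slow sarcomere genes, looked up after the data were seen, were among those that did not pass, with log2 fold changes of -0.12 ± 0.31 for Myh7, -0.37 ± 0.26 for Myl2, -0.050 ± 0.20 for Myl3, 0.18 ± 0.22 for Tnnt1, -0.22 ± 0.25 for Tnni1 and 0.32 ± 0.28 for Tnnc1. The mean log2 CPM of the slow list was 7.96 in SMA 3 and 7.89 in SMA 4, within the wild type range of 6.81 to 7.99. It was 8.22 in SMA 1 and 8.17 in SMA 2, and wild type 5 was the lowest library. The slow list had a camera adjusted p of 0.0305, and adjusted p = 0.704 with an estimated correlation. Its camera call was lost under scaling to total counts, at 0.114, without wild type 5, at 0.0797, and without wild type 5 and SMA 3 together, at 0.0703.

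The balance of myosin heavy chain transcripts shifted from Myh4 towards Myh8 and Myh1. As shares of the counts of 6 Myh genes, Myh4, the adult IIb chain, took 87.0% ± 2.82 in wild type (SD, n = 5) and 65.5% ± 3.26 in SMA (SD, n = 4; two-sided exact permutation test, p = 0.00794, adjusted p = 0.0159). Myh8, the perinatal chain, took 0.978% ± 0.233 and 12.8% ± 3.29, and Myh1, the IIx chain, 8.78% ± 1.61 and 17.2% ± 2.76, with the same exact and adjusted p as Myh4. The share of Myh3, the embryonic chain, was 0.108% ± 0.0794 and 0.267% ± 0.0724 (exact permutation test, p = 0.0318, adjusted p = 0.0476), and the unadjusted exact p was 0.0857 without wild type 1, 3, 4 or 5, 0.0893 without SMA 1 and 0.107 without SMA 2. Shares of Myh2, 2.14% ± 0.483 and 2.64% ± 0.336 (exact p = 0.103), and of Myh7, 0.991% ± 0.573 and 1.58% ± 0.346 (exact p = 0.111), did not pass, although Myh7 had an exact p of 0.0286 without wild type 2. Fitted against all genes, Myh8 rose by 2.89 ± 0.30 and Myh4 fell by 1.24 ± 0.16, while Myh1 had a log2 fold change of 0.15 ± 0.16 and Myh3 of 0.57 ± 0.38 with adjusted p-values of 0.471 and 0.22 by edgeR's quasi-likelihood test, and Myh3 passed without wild type 2, at 0.021. These genes have similar sequences and neighbour each other on chromosome 11 apart from Myh7, so reads may have been divided among them.

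**Figure D2:**
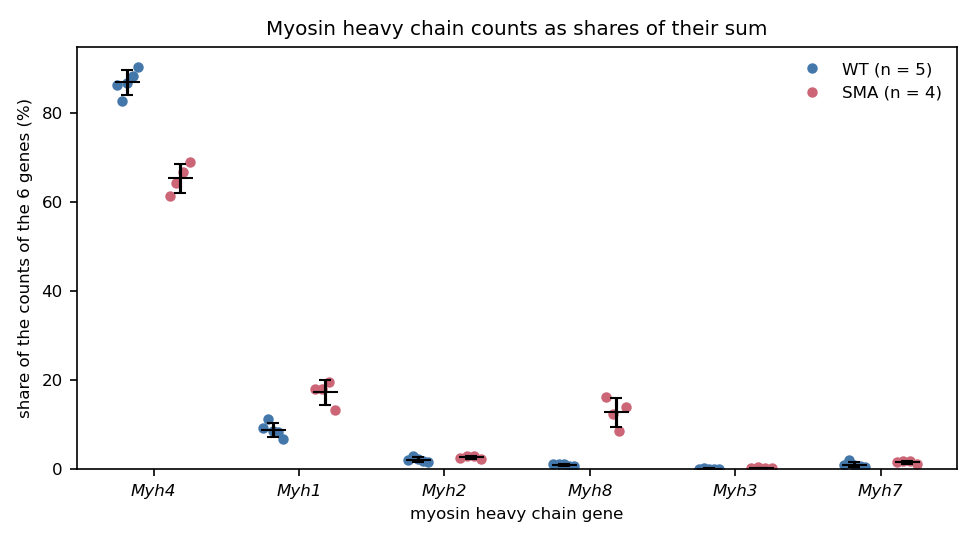
Shares, in percent on the vertical axis, of the counts of 6 myosin heavy chain genes in each library, with points for libraries, bars for group means and error bars for SD (wild type n = 5, SMA n = 4). Myh4 fell from 87.0% to 65.5% on average and Myh8 rose from 0.978% to 12.8%.

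Genes that mark immature muscle did not move as 1 block. Of 17 measured developmental muscle genes, 11 rose, 3 fell and 3 did not pass (11 and 3 adjusted over the list alone). The mean log2 CPM of the list was 6.20 in SMA 3, within the wild type range of 5.46 to 6.31, and 6.63 to 6.85 in the other SMA libraries. Wild type 5 was the lowest, against 6.09 to 6.31 in the other wild type libraries. Myh8 at 2.89 ± 0.30 and Igf2, a fetal growth factor gene, at 0.95 ± 0.19 rose, while Actc1, the actin of embryonic and cardiac muscle, at -3.98 ± 0.20 and Tmem8c, now named Mymk and needed for myoblast fusion, at -1.65 ± 0.16 fell. The camera adjusted p was 0.0311, and adjusted p = 0.704 with an estimated correlation. The call was lost under scaling to total counts at 0.233, with a stricter low-count filter at 0.0536, with sex as a covariate at 0.0618 and without SMA 1 at 0.0528. The 20 myogenic regulators held 4 that rose, 5 that fell and 11 that did not pass (4 and 5 adjusted over the list alone), with Tmem8c and the repressor gene Hes6, at -0.79 ± 0.096, among those that fell. That list was not called by camera (adjusted p = 0.453), and its median log2 fold change of -0.12 turned to 0.12 under scaling to total counts. Of 13 satellite cell genes, 5 rose, 3 fell and 5 did not pass (5 and 3 adjusted over the list alone), with the proteoglycan gene Sdc4 at 0.92 ± 0.083, and camera did not call the list (adjusted p = 0.509).

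Fatty acid oxidation genes were higher and glycolysis genes lower, and respiration genes were lower by camera although 1 SMA library lay within the wild type range. Of 28 measured fatty acid oxidation genes, 21 rose, 0 fell and 7 did not pass (22 and 0 adjusted over the list alone). Acot2, a mitochondrial acyl-CoA thioesterase gene, rose 8.02-fold, from 7.97 ± 0.883 to 64.0 ± 8.44 CPM (SD, n = 5 and 4), and Cpt1b, which carries fatty acids into mitochondria, rose by 1.15 ± 0.088 on the log2 scale. Camera gave an adjusted p of 1.97e-06, and adjusted p = 0.467 with an estimated correlation. Of 55 nuclear genes of oxidative phosphorylation, 27 fell, 1 rose and 27 did not pass (27 and 1 adjusted over the list alone), with Cycs at -0.85 ± 0.16 and Ndufb10 at -0.65 ± 0.13, and the median of -0.27 was -0.026 under scaling to total counts. The mean log2 CPM of the list was 8.54 in SMA 3, within the wild type range of 8.41 to 8.78, and 8.24 to 8.27 in the other SMA libraries. Cycs had 306 CPM and Ndufb10 264 CPM in SMA 3, against 198 to 212 and 170 to 180 CPM in the other SMA libraries. This list had a camera adjusted p of 3.83e-04, and adjusted p = 0.704 with an estimated correlation. The 13 listed mitochondrially encoded genes had no matching entry and were not analysed here. Of 23 glycolysis and glycogen genes, 12 fell, 2 rose and 9 did not pass (12 and 2 adjusted over the list alone), and their median of -0.39 was -0.14 under scaling to total counts. Gpd1, a glycerol phosphate dehydrogenase gene, fell by 1.56 ± 0.14, while the insulin-responsive glucose transporter gene Slc2a4 rose by 1.09 ± 0.097. The glycolysis list had a camera adjusted p of 0.00796, and adjusted p = 0.704 with an estimated correlation, and its preset call was lost without wild type 5 and SMA 3 together, at 0.0517.

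Genes induced by glucocorticoids and by the transcription factor KLF15 were higher. Of 22 measured members, 15 rose, 3 fell and 4 did not pass (16 and 3 adjusted over the list alone), with a median of 1.58. Fkbp5, a chaperone gene that responds to glucocorticoids, rose by 3.28 ± 0.15, Mt1 by 4.02 ± 0.17, Klf15 by 2.09 ± 0.21 and Prodh, a proline degradation gene, by 3.75 ± 0.21. The camera adjusted p was 5.86e-05, and adjusted p = 0.467 with an estimated correlation. Of 19 circadian clock genes, 9 rose, 3 fell and 7 did not pass (9 and 3 adjusted over the list alone). Per1 rose by 1.73 ± 0.36, and by 2.33 without wild type 5 and SMA 3, Bhlhe41 fell by 1.55 ± 0.086, and camera did not call the list (adjusted p = 0.275). The hour of tissue collection was not stated in the labels.

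Cell division genes were lower almost throughout. Of 32 measured cell cycle genes, 31 fell, 0 rose and 1 did not pass (31 and 0 adjusted over the list alone), with a median of -1.59. Top2a, a topoisomerase gene of dividing cells, fell by 2.50 ± 0.13, from 35.9 ± 3.34 to 6.32 ± 1.15 CPM (SD, n = 5 and 4). The proliferation marker Mki67 changed by -2.20 ± 0.14 and the mitotic kinase gene Aurka by -1.95 ± 0.11. Camera gave an adjusted p of 3.05e-16, and adjusted p = 0.467 with an estimated correlation, where the unadjusted p was 0.0215. It was the 1 list of 38 with an unadjusted p under 0.05 in that version of the test, in which 0 lists passed after adjustment. With the preset correlation 9 lists were higher and 11 lower.

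Matrix and connective tissue genes were lower. Of 30 measured extracellular matrix genes, 22 fell, 1 rose and 7 did not pass (22 and 1 adjusted over the list alone). The collagen genes Col1a1 and Col3a1 fell by 1.54 ± 0.30 and 0.64 ± 0.16, the cross-linking enzyme gene Loxl1 by 1.02 ± 0.13 and the fibrillin gene Fbn1 by 0.98 ± 0.15. The matrix list had a camera adjusted p of 3.69e-04, and adjusted p = 0.704 with an estimated correlation. Of 15 fibroblast and fibro-adipogenic progenitor genes, 11 fell, 2 rose and 2 did not pass (12 and 2 adjusted over the list alone), with Dpep1 at 2.09 ± 0.16 among those that rose. That list had a camera adjusted p of 0.0311, and adjusted p = 0.704 with an estimated correlation, and lost its preset call without wild type 2, at 0.0604. All 10 tendon genes fell (10 and 0 adjusted over the list alone), among them the tendon transcription factor gene Scx at -1.59 ± 0.16, with a camera adjusted p of 0.00113, and adjusted p = 0.594 with an estimated correlation. The matrix list shares members with both the fibroblast and the tendon list, so these falls are not separate results. Of 12 cartilage and bone genes, 8 fell, 0 rose and 4 did not pass (8 and 0 adjusted over the list alone). Those that fell included the alkaline phosphatase gene Alpl at -2.53 ± 0.42. The mean log2 CPM of the list was 3.21, 2.79 and 1.32 in wild type 1, 2 and 5. It was only 0.23 and 0.31 in wild type 3 and 4, close to the SMA range of -0.29 to 0.30. The camera adjusted p of that list was 0.0311, and adjusted p = 0.704 with an estimated correlation. Its median of -1.92 became -1.31 without wild type 1 and -1.19 without wild type 2, where the preset call was lost at 0.0606, as it was with a stricter low-count filter (0.073), upper-quartile scaling (0.0555), limma-voom (0.0648) and sex as a covariate (0.0725). Bglap, the bone matrix protein osteocalcin, had 111 CPM in wild type 1 and between 0.14 and 19.1 CPM in the other wild type libraries, and its change of -6.40 ± 1.73 became -4.22 without wild type 1. Bglap in wild type 3 and 4, at 0.30 and 0.14 CPM, lay within the SMA range of 0.13 to 0.63 CPM. Its adjusted p of 0.00797 by edgeR's quasi-likelihood test became 0.272 with limma-voom, 0.07 with limma-trend and 0.209 with sex as a covariate, where its change was -3.51, -3.52 and -4.25.

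Protein folding and interferon genes were lower. Of 20 measured endoplasmic reticulum folding genes, 12 fell, 1 rose and 7 did not pass (12 and 2 adjusted over the list alone), with Pdia6 at -0.73 ± 0.069 and Manf at -0.78 ± 0.090. The folding list had a camera adjusted p of 0.0109, and adjusted p = 0.467 with an estimated correlation. Its median of -0.32 was -0.091 under scaling to total counts. Of 20 interferon response genes, 14 fell, 1 rose and 5 did not pass (14 and 1 adjusted over the list alone), including Isg15 at -2.02 ± 0.28 and Usp18 at -1.73 ± 0.26. Both were low, with means of 1.15 and 1.48 CPM in wild type and 0.28 and 0.45 CPM in SMA. The interferon list had a camera adjusted p of 6.72e-04, and adjusted p = 0.476 with an estimated correlation. Its median of -0.63 was -0.39 under scaling to total counts.

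Several signalling and synthesis groups had members moving both ways, and camera called none of them. In the integrated stress response list 6 of 22 rose and 5 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.509), with the cysteine synthesis gene Cth at 2.36 ± 0.18 and the proline synthesis gene Pycr1 at -1.68 ± 0.11. In the insulin-like growth factor list 8 of 19 rose and 7 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.727). The activin receptor gene Acvr2b rose by 2.06 ± 0.21 and the insulin receptor gene Insr by 0.74 ± 0.080. Igf1 fell by 0.31 ± 0.11 with an adjusted p of 0.0328 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and did not pass without wild type 2 (0.0688), wild type 4 (0.0761), SMA 2 (0.07), SMA 3 (0.0519) or SMA 4 (0.0879), nor under scaling to total counts (0.632) or with sex as a covariate (0.141). In the sterol synthesis list 3 of 19 rose and 8 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.466), with Fdft1 at 1.61 ± 0.080 and Lss at 1.20 ± 0.11. Its median of -0.31 and its mean of -0.0022 were both negative, while the rotation test fry had the upward direction. Of 15 immediate early genes, 2 rose, 3 fell and 10 did not pass (2 and 3 adjusted over the list alone; camera adjusted p = 0.872), with Egr2 at 1.14 ± 0.18, a median of -0.028 that turned to 0.21 under scaling to total counts, and fry in the upward direction.

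Partners of SMN in splicing ribonucleoprotein assembly changed little as a group. Of 9 SMN complex genes, 3 fell, 1 rose and 5 did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.306). Beside Smn1, Gemin7 fell by 0.68 ± 0.090, and the median of -0.18 turned to 0.060 under scaling to total counts. Of 15 small nuclear ribonucleoprotein core and assembly genes, 3 fell, 1 rose and 11 did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.414). Snrpd1 fell by 0.68 ± 0.11 and Snrpd3 rose by 0.39 ± 0.071, and the median of -0.077 turned to 0.17 under scaling to total counts.

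Among markers of other cell types, those of Schwann cells, which ensheath peripheral axons, were higher. Of 15 measured members, 12 rose, 0 fell and 3 did not pass (12 and 0 adjusted over the list alone). The myelin gene Mbp rose by 1.66 ± 0.30, from 99.3 ± 40.4 to 314 ± 114 CPM (SD, n = 5 and 4), and the neuregulin receptor gene Erbb3 by 1.35 ± 0.14. The camera adjusted p was 3.83e-04, and adjusted p = 0.594 with an estimated correlation. Red cell genes were lower, with 7 of 7 measured erythroid genes falling (7 and 0 adjusted over the list alone), among them the transferrin receptor gene Tfrc at -2.16 ± 0.28, which muscle also expresses. The erythroid list had a camera adjusted p of 0.00279, and adjusted p = 0.467 with an estimated correlation.

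The remaining cell type lists were not called by camera. Of 17 macrophage genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.101), with the mannose receptor gene Mrc1 at -1.72 ± 0.10, and the list passed without wild type 3 (0.0456), without SMA 1 (0.0381) and with no low-count filter (0.033). Endothelial genes numbered 15, of which 2 fell and 1 rose, Robo4 at 0.85 ± 0.083 (1 and 1 adjusted over the list alone; adjusted p = 0.489), and their median of -0.079 turned to 0.16 under scaling to total counts. Of 13 smooth muscle and pericyte genes, 4 fell, among them Rgs5 at -1.18 ± 0.090, and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.306), and their median of -0.062 turned to 0.16 under scaling to total counts. Of 15 white adipocyte genes, 6 rose and 3 fell (6 and 3 adjusted over the list alone; adjusted p = 0.489), with the lipid droplet gene Plin4 at 2.30 ± 0.17. Their median of -0.11 differed in sign from the upward camera direction, turned to 0.14 under scaling to total counts and was 0.61 without wild type 5. Of 9 brown adipocyte genes, 3 rose and 3 fell, Ucp1 among the latter (3 and 3 adjusted over the list alone; adjusted p = 0.832). Of 6 neutrophil and granulocyte precursor genes, 1 rose, Lcn2 at 3.12 ± 0.35, and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.872), with a median of -0.36, an upward camera direction and a median of 0.46 without wild type 1. Of 5 lymphocyte genes, 2 fell and 0 rose, Cd79b at -1.13 ± 0.26 (1 and 0 adjusted over the list alone; adjusted p = 0.313). Of 7 keratinocyte genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.336), with Trp63 at 1.21 ± 0.12. The 4 Y-linked genes had 0 calls (0 and 0 adjusted over the list alone; adjusted p = 0.272), Uty among them at -2.48 ± 1.27 with an adjusted p of 0.116 by edgeR's quasi-likelihood test. Without SMA 2, the 1 SMA library that expressed them, the Y-linked list passed at 0.0436, its median of -1.84 becoming -9.45, and Uty passed at 9.8e-04 by edgeR, with -9.44. The list passed at 0.0449 under scaling to total counts, and its median was -5.68 with limma-voom, -5.34 with limma-trend and -0.19 with sex as a covariate. Uty also passed with limma-trend, at -5.22 with an adjusted p of 0.0355, and in edgeR with sex as a covariate, at -0.84 with 0.0196, while limma-voom gave -5.56 with an adjusted p of 0.231. The values without SMA 2 rest on levels near 0, since SMA libraries other than SMA 2 held Uty at no more than 0.0286 CPM. How far the fitted values depend on the prior count was not tested.

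**Figure D3:**
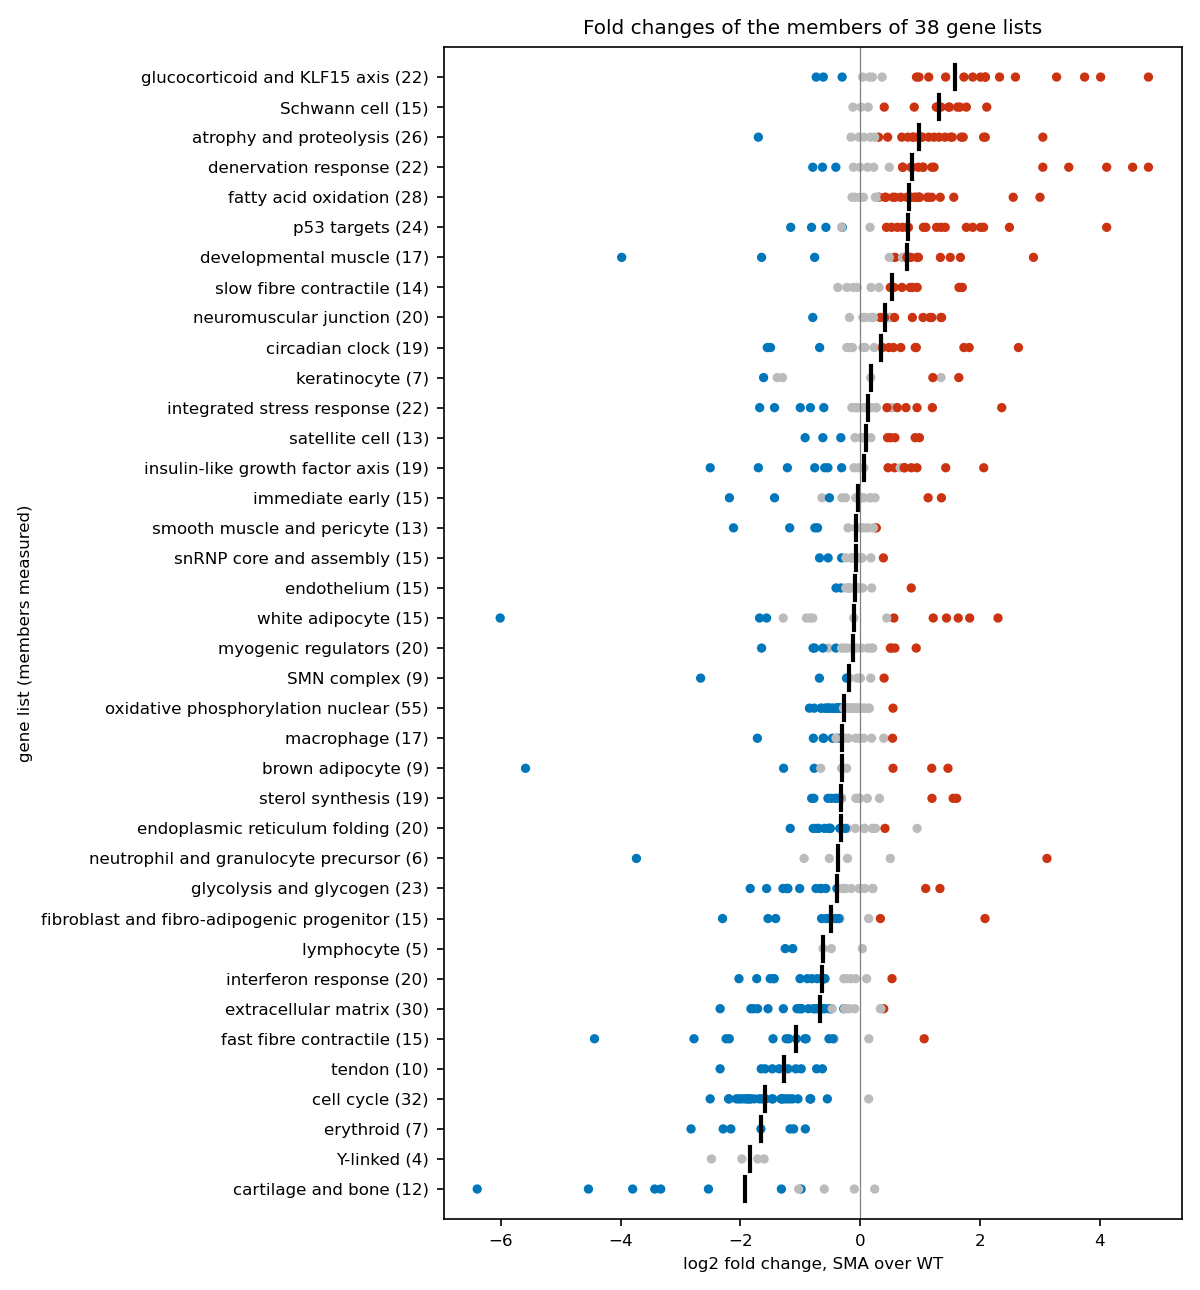
Log2 fold change of SMA over wild type, on the horizontal axis, for each measured member of 38 gene lists, given by name with the number of members on the vertical axis, with red points for members that rose, blue for members that fell, grey for members that did not pass and black bars for list medians. The cell cycle list had a median of -1.59 with 31 of 32 members falling, and the Schwann cell list a median of 1.32 with 12 of 15 members rising.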

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

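Both tests of the Schwann rise and the test of blood-forming cells were chosen only after the result was seen, as was the reading of the planned fit with sex as a covariate as a test of the calls. Of 208 groups of values, 18 held a library whose gap to its nearest neighbour, as a share of the group's range, exceeded Dixon's critical value, where chance gives about 1 in 20, or 10.4. The groups included genes chosen after their values were seen, with Bglap, Lep, Per1 and Col3a1 among those flagged. The genes are also not independent of each other, so 10.4 is only a rough guide.

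SMA 3 stood apart in 6 of these. Its gap was 0.871 of the range for Cycs (306 CPM against 198 to 212), 0.886 for Ndufb10 (264 against 170 to 180), 0.855 for Fbn1 (79.3 against 101 to 105), 0.901 for Acvr2b (6.71 against 11.8 to 12.4) and 0.923 for Col3a1 (1129 against 1693 to 1740). Untested genes took 0.148% of its counts against 0.0562% to 0.0687% in the other SMA libraries, a gap of 0.863.

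Wild type 5 stood apart in 5 groups. The gap was 0.718 for Myog (140 CPM against 115 to 122), 0.727 for Ucp1 (119 against 11.3 to 40.8), 0.906 for F830016B08Rik (28.9 against 2.13 to 4.66), 0.819 for Lep (4.82 against 0.315 to 1.13) and 0.780 for Per1 (100.5 against 32.9 to 47.8). Wild type 4 was low for Smn1 (11.1 CPM against 13.1 to 13.8, gap 0.738) and high for Mt2 (7.48 against 3.93 to 4.84, gap 0.744). Wild type 1 was low for Cblb (17.8 against 19.7 to 20.4, gap 0.740) and high for Bglap (111 against 0.14 to 19.1, gap 0.8293). Wild type 3 was high for Chrnb1 (173 against 150.5 to 156, gap 0.739) and wild type 2 for Scx (10.03 against 6.84 to 7.69, gap 0.734). Uty was expressed in SMA 2 at 15.8 CPM against 0.0280 to 0.0286 in the other SMA libraries, a gap of 1.

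The first pattern weighed was the number of genes called. Of 100 splits of the 9 libraries into 4 and 5, 1 gave as many genes as the 8712 of the real one, namely the real one itself. Likewise 1 of 100 gave as many as the 2309 with at least a 2-fold change. That is the smallest share that 100 splits can give, so chance cannot be excluded by it. Splits that mix the groups carry any group difference as spread, and the median of the other splits was 0 genes. The highest other split gave 4650 and 1257 genes. It set 4 wild type libraries against the remaining wild type library with all SMA libraries, so it largely repeats the real division. With sex as a covariate 78.5% of the calls remained in the same direction, and after thinning every library to 24917665 counts 95.5% remained, which argues against sex and depth as the whole cause, while age, litter and dissection, which the labels do not give, stay open.

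The second pattern was the rise of Schwann cell genes. A lower share of muscle fibre RNA alone would raise markers of other cell types alike. The Schwann score minus the mean score of endothelium, fibroblasts, macrophages and smooth muscle was higher in SMA by 1.39 on the log2 scale (exact permutation test, p = 0.00794). Medians of these 4 lists, -0.079, -0.48, -0.30 and -0.062, were known when the contrast was chosen, so its outcome was largely fixed. A lower fibre share joined by a fall of those cell types was not excluded. More nerve in the dissected tissue cannot be told apart from a change within Schwann cells, since the interquartile range of the members' fold changes, 0.906, lay between what the explanation requires and what would exclude it. A biological difference in nerve or Schwann cells of SMA muscle may also account for it and was not tested further. Of the 15 members, 1 is also in another list, and all were measured in wild type muscle too, with Mbp at 99.3 CPM there.

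The third pattern was the fall of cell cycle genes. After a trend over GC content and transcript length was removed, the median of the list was -1.53 against -1.59 before, with values for 100% of its members, so such a trend does not account for it. Loss of blood-forming cells cannot be told apart, since erythroid genes fell with a median of -1.66 while the median of neutrophil and precursor genes was -0.36. Slower growth of SMA muscle is a biological candidate that may fit and was not tested.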

How the results depend on the processing

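The fit without wild type 5 and SMA 3, the test of myosin shares and the count of detected genes after thinning were chosen only after the result was seen. Of 98 genes selected for naming, 92 kept their direction and side of the threshold in all alternatives in which they were tested, and none turned direction. Many of them were selected by low p, large change or values already seen in these libraries, so this stability was largely fixed by the selection. Among all calls, 78.5% were kept in the same direction with sex as a covariate and 75.3% under total counts alone. Of 38 lists, 26 kept their camera direction and side of the threshold, although the medians of some turned under total counts. No gene passed in opposite directions in any of 21 alternatives. Counts of changed genes ran from 6883 (sex as a covariate) to 9422 (without wild type 5 and SMA 3) around 8712, and from 7655 (without SMA 1) to 9083 (without SMA 3) with 1 library left out. Under total counts alone 2164 genes were lower, 2019 were higher and 625 lower at least 2-fold, against 4319, 1312 and 997, since that scaling shifted the median of all genes by 0.23. That scaling turned the camera direction of growth factor (median 0.30), white adipocyte (0.14) and neutrophil (-0.12) genes, none called. Immediate early genes turned with sex as a covariate (0.27) and without wild type 5 and SMA 3 (0.36), and the cause was not tested. With 1 library left out, medians ranged from -0.15 to 0.16 for immediate early, -0.43 to 0.041 for brown adipocyte and -0.57 to 0.46 for neutrophil genes, each turning in at least 1 case.

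Same-numbered libraries of both groups had correlations of 0.118, -0.0055, -0.048 and 0.097, within the range of -0.318 to 0.174 for other pairs. No sign of pairing by number was therefore seen, but so few values cannot exclude it. With a replicate block 7879 genes passed, brown adipocyte (0.050) and immediate early (0.19) medians turned, the slow fibre call was lost (0.0841), the macrophage list passed (0.0471) and Uty passed in edgeR (-3.85, adjusted p = 0.0345). Leaving out haemoglobin genes gave 8709 genes, while leaving out mitochondrial genes was not run, as none matched. SMA libraries held 754.6 more genes with at least 1 read, 623.9 more after thinning to the smallest total, and 561.9 more with at least 10 reads after thinning. At these depths and this number of libraries 56.7% of simulated 1.5-fold changes were recovered, and thinning kept 95.5% of the calls, so most calls did not rest on the depth above the smallest total.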

Other observations

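The test of delayed maturation, with the way it was read, was chosen only after the result was seen, and the test of genes near Smn1 before. Among genes with large changes, some neighbours changed in the same direction. Mt2 and Mt1, close together on chromosome 8, rose by 4.81 and 4.02 on the log2 scale. Tmem82 and its antisense AI507597 rose by 4.46 and 4.80 on the log2 scale, C130080G10Rik and Actc1 changed by -5.22 and -3.98, and Gm4841 and F830016B08Rik by -5.49 and -5.02. The strand setting of the counting is not given in the sources used here, so the values of the overlapping Tmem82 and AI507597 are not known to be separate measurements. Actc1 and C130080G10Rik do not overlap in GENCODE M21, and whether they shared reads was not tested.

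One hypothesis was that SMA muscle may show a uniform delay of maturation, since Myh8 rose and adult fast-fibre genes fell. A uniform delay of muscle maturation would raise most developmental muscle genes and lower none. Of 17 measured members, 11 rose and 3 fell, namely Actc1 at -3.98 ± 0.20 (SE), Tmem8c at -1.65 ± 0.16 and Gm7325, now named Mymx, at -0.76 ± 0.18. The threshold was set over all tested genes, and it would allow 0.7 false calls among those called only if its rate held within this list. All 3 also fell under scaling to total counts. Falls in this list had been seen when the test was written, so the test adds no evidence beyond these values. They differ from what a delay of every listed gene would give, while a delay of part of the program stays open.

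Another hypothesis was that DNA of another strain beside the modified Smn1 allele could alter neighbouring genes. Within 10 Mb of Smn1, 45 of 95 tested genes had passed against 7858 of 14132 elsewhere, an odds ratio of 0.719 (Fisher's exact test, two-sided, p = 0.12). No excess near Smn1 was detectable, and a small effect cannot be told apart from none at this number of genes.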
